A study of Mus musculus with 24 samples.

How the data were processed

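Gene expression was measured by RNA sequencing of whole sciatic nerve from 24 mouse samples in 4 groups of 6. Groups were read from the treatment label of each sample, and samples are named by group and a number from 1 to 6 that only names them. Per the labels' protocols, total RNA was purified with a Qiagen RNeasy column kit, and 100 ng went into Roche KAPA RNA HyperPrep libraries amplified for 15 cycles after ribosomal RNA removal with the QIAseq FastSelect kit. The molecule label reads polyA RNA, while the kit removes ribosomal RNA and does not select polyA; the labels do not settle which holds.

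The authors deposited raw counts of reads per gene, with a column per sample and no pooling or scaling. Per the submitters' processing notes, FastQC, STAR and DESeq2 were used and the genome build was mm10; the counting program, the gene annotation, the versions and the strand setting are not given in the sources used here. The 24421 gene symbols in the table were matched to the RefSeq annotation of GRCm38.p6, which has the coordinates of mm10, and 23204 (95.0%) matched. Of all genes 1000 had a count of 0 in every library.

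Total counts per library ranged from 5391543 to 42321550. A count of 3, taken as the floor of detection, was 0.556 CPM in the shallowest library (vehicle 3) and 0.0709 CPM in the deepest (vehicle 2). Floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Among the 60 pairs of libraries within groups the lowest chi-square per degree of freedom was 18.9, so no library was a repeat of another of its group within sampling noise.

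Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr at its settings of a minimum count of 10 and a minimum total of 15, which left 15385 genes holding at least 98.6% of the counts of every library. Libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 24 libraries with a mean per group, which left 20 residual degrees of freedom. The common dispersion was 0.129, a biological coefficient of variation of 35.9%. The 7 contrasts were each treatment against vehicle, the combination against each single drug, ERKi against CDKi, and the interaction, combination minus ERKi minus CDKi plus vehicle. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of a contrast, with a threshold of 0.05. Standard errors were the log2 fold change divided by the square root of the F statistic. CPM are TMM-scaled, and log2 CPM of single libraries used a prior count of 2.

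Gene lists were fixed before the data were examined, as were the model, the contrasts, the alternatives to be tried and the rule for named genes. The 35 lists covered ERK pathway output, immediate early genes, E2F and DNA replication, G2/M and mitosis, the CDK4/6 axis, p53 targets, myelin, non-myelinating and repair Schwann cells, pan Schwann cells, cholesterol synthesis, fatty acid synthesis, extracellular matrix, nerve fibroblasts, perineurial cells, endothelial cells, pericytes and smooth muscle, macrophages, monocytes and neutrophils, mast cells, T and NK cells, B and plasma cells, dendritic cells, adipocytes, skeletal muscle, red blood cells, neurons and axons, type I interferon response, MHC class I and class II presentation, chemokines, receptor tyrosine kinases and ligands, glucocorticoid response, circadian clock, heat shock and mitochondrially encoded genes. Of these, 33 had at least 3 tested members. Red blood cells had 2 tested members, and the 13 mitochondrially encoded genes had 0 in the table, so these 2 were not analysed as lists. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. Adjustment was over the 33 lists of a contrast. Lists of 20 liver genes and 8 satellite glia genes were added after the data were seen.

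Genes named in every comparison with vehicle were Nf1, Postn, Dusp6, Spry4, Etv5, Ccnd1, Mki67, Top2a, Mcm5, Rrm2, Cdkn1a and Cdkn2c. To these were added, per comparison with vehicle, the 6 highest and 6 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and at least 5 of 6 treated libraries on the same side of the vehicle mean. The 2 members with the smallest p of each called list were added too, and 4 genes per direction in the other comparisons. Sex-linked transcripts, immunoglobulin and T cell receptor segments, predicted genes and pseudogenes were left out of the rule. The result of 1 named gene is not reported here.

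The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights (limma 3.58.1), RLE and upper quartile scaling, no count filter, a CPM above 1 in 6 libraries, only the groups compared, and terms for the number series of the titles, for sex read from Xist and Y-linked counts, and for the muscle and adipocyte lists. DESeq2 was run on all 23421 genes with a count in any library and not on the 15385 kept genes, so program and filter changed together. Each of the 24 libraries was also left out in turn. The term for sex put libraries with over 100 CPM of Y-linked transcripts in 1 class, and is uncertain for ERKi 3, CDKi 2 and CDKi 3, where Xist and Y-linked transcripts occurred together. Alternatives added after seeing the data were leaving out each library for lists other than the ERK, E2F and mitosis lists, a neuron list covariate, leaving out the 3 liver-positive libraries, the 6 neuron-poor libraries or the deepest and shallowest libraries, the first 2 of these together, and thinning every library to 5391543 counts.

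The model was tested on simulated counts for the combination against vehicle, over 15385 genes. They used the mean of each gene over all 24 libraries and the real library sizes and groups. In 8 sets with 200 changed genes each it recovered 20.8% of genes changed 1.5-fold, 62.5% at 2-fold and 84.5% at 4-fold, and 37 of 922 calls (4.01%) were false. In 4 sets without change it made 1 call. Genes were drawn independently, while in the real libraries sets such as neuronal and liver transcripts move together. These rates may therefore not hold for the real libraries.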

Results

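Gene expression was measured by bulk RNA sequencing in sciatic nerve from mice with floxed Nf1 alleles and a Cre recombinase driven by Postn. Nf1 encodes neurofibromin, a negative regulator of RAS and thereby of ERK signalling, and the labels give the tumour stage as plexiform neurofibroma, a benign tumour of the nerve sheath. Mice had received vehicle, the ERK1/2 inhibitor LY3214996 (ERKi), the CDK4/6 inhibitor abemaciclib (CDKi) or both drugs (combination) for 1 week. Each of the 4 groups held 6 libraries, 24 in all. Total counts per library ranged from 5391543 (vehicle 3) to 42321550 (vehicle 2). The ranges were 14525128 to 24676846 in ERKi, 15118837 to 19757307 in CDKi and 12096063 to 18518610 in the combination. Of 24421 genes in the table, 15385 had enough counts to be tested. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these samples.

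Nf1 itself was measured at 359 ± 48.8 CPM in vehicle, 392 ± 37.2 in ERKi, 335 ± 25.6 in CDKi and 341 ± 27.1 in the combination (mean ± SD, n = 6 each). The labels give all groups the same genotype, so these values do not check the deletion. No treated group differed from vehicle in Nf1 by edgeR's quasi-likelihood test (adjusted p = 0.674, 1 and 0.832).

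The libraries differed widely in neuronal transcripts. Nefl, which encodes the neurofilament light chain, ranged from 1.86 to 1530 CPM. Scn10a, a sodium channel gene of sensory neurons, ranged from 0.215 to 634 CPM, and Prph, which encodes the neuronal filament peripherin, from 1.64 to 317 CPM. The mean log2 CPM of 10 neuron genes spanned 1.67 to 8.22 in vehicle, 7.66 to 9.55 in ERKi, 1.51 to 8.27 in CDKi and 2.29 to 8.70 in the combination. The libraries below 6 on this scale were vehicle 1 and 5, CDKi 3 and 5, and combination 3 and 5. In a principal component analysis the first component held 49.3% of the variance, and the group accounted for 14.2% of that component. It followed the neuron list mean, with a Pearson r of 0.968 over the 24 libraries. Liver transcripts stood out in ERKi 3, CDKi 1 and CDKi 3, where Alb, the gene for serum albumin, reached 4543, 3155 and 4534 CPM against at most 1.607 CPM in every other library. The adipocyte list averaged 1.41 ± 0.949 log2 CPM in vehicle, 2.40 ± 0.944 in ERKi, 3.26 ± 0.543 in CDKi and 2.75 ± 0.493 in the combination. The skeletal muscle list was highest in CDKi 5, at 5.27 log2 CPM. Y-linked transcripts exceeded 100 CPM in 14 libraries (4 vehicle, 3 ERKi, 4 CDKi and 3 combination). Xist and Y-linked transcripts occurred together in CDKi 2, at 767 and 219 CPM, and in ERKi 3 and CDKi 3, at 882 with 16.2 CPM and 3037 with 16.6 CPM.

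**Figure D1:**
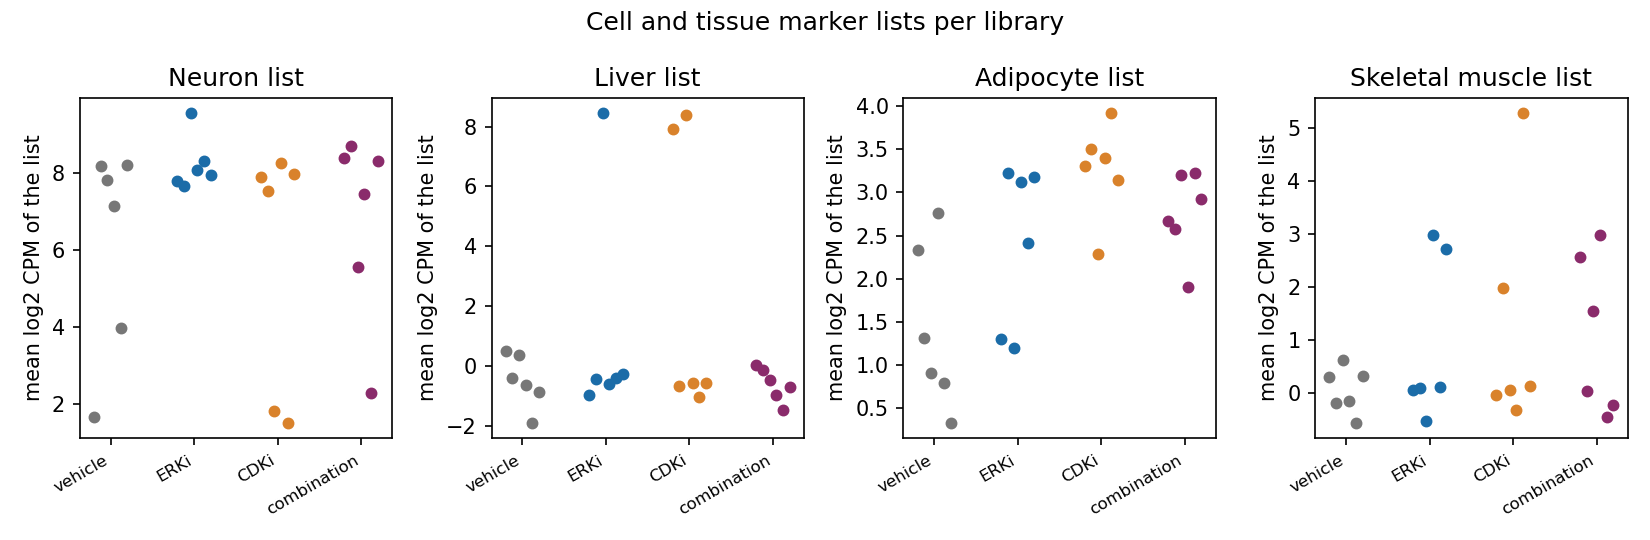
Mean log2 CPM of the neuron, liver, adipocyte and skeletal muscle lists, with a point for each of the 6 libraries of every group. The 3 libraries with liver transcripts lie between 7.92 and 8.44 on the liver list, and the neuron list spans 8.03 log2 units over all libraries.

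The first comparison asked what ERK1/2 inhibition alone changed in the nerve. No single gene passed after ERKi. Dusp6, a phosphatase induced by ERK that switches ERK off, was at 167 ± 42.4 CPM in ERKi and 218 ± 31.5 CPM in vehicle (log2 fold change -0.38 ± 0.19 SE, adjusted p = 0.672, lower in 5 of 6 libraries). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, had a log2 fold change of -0.26 ± 0.32 (adjusted p = 0.767), and Etv5, an ETS factor induced by ERK, one of 0.09 ± 0.22 (adjusted p = 0.895). Ccnd1, the cyclin D1 gene, was at -0.33 (adjusted p = 0.747), the proliferation marker Mki67 at -0.24 (adjusted p = 0.876) and Postn, which encodes the matrix protein periostin, at -0.62 (adjusted p = 0.672). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes changed. The count at an unadjusted p under 0.05 was 975, DESeq2 called 11 genes, all higher, and limma-voom called 0.

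As groups, 15 of 33 gene lists differed from vehicle after ERKi by camera with a preset correlation, 3 higher and 12 lower, and 0 did with an estimated correlation, where the smallest adjusted p was 0.564. ERK pathway output genes were lower in 16 of 21 members (median -0.24, camera adjusted p = 0.0125, adjusted p = 0.564 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. That call was lost without vehicle 1 (median -0.09, adjusted p = 0.0985) and without ERKi 4 (median -0.24, adjusted p = 0.0535). All 6 ERKi libraries were rich in neuronal transcripts: the median was -0.097 with the neuron list as a covariate (adjusted p = 0.0359) and -0.068 without the 6 neuron-poor libraries, where the call was lost (adjusted p = 0.176), both settings chosen after seeing the data. Extracellular matrix genes were lower in 27 of 28 members (median -0.61, camera adjusted p = 4.35e-12), among them Loxl1, which crosslinks elastin (-0.60 ± 0.24), and the metalloprotease gene Mmp14 (-0.52 ± 0.21). Myelin genes were lower in 21 of 21 members (median -0.33, camera adjusted p = 2.19e-06), including Egr2, the master regulator of myelination (-0.58 ± 0.28). ERKi 3 stood apart on this list, at 6.95 log2 CPM against 8.35 to 9.03 in the other ERKi libraries. Without ERKi 3 the myelin median was -0.14 (adjusted p = 0.00934). Without the 3 liver-positive libraries and with the neuron list as a covariate the myelin call was lost (median -0.030, adjusted p = 0.587), and the matrix median was -0.31 (adjusted p = 1.52e-04). Both settings were chosen after seeing the data. Nerve fibroblast genes were lower in 8 of 12 (median -0.47, Apod, an apolipoprotein gene, -0.68 ± 0.23), glucocorticoid response genes in 11 of 12 (median -0.49, Sgk1 -1.03 ± 0.40) and circadian clock genes in 13 of 14 (median -0.28, Ciart -0.998 ± 0.412). For each of these lists the adjusted p was 0.564 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The other lists called lower were immediate early genes (14 of 16, Cyr61 -0.60), macrophages (15 of 16, Mertk -0.67), chemokines (12 of 16, Il33 -0.65), pan Schwann cells (8 of 9, Gpr37l1 -0.43), type I interferon response (20 of 22) and MHC class I presentation (9 of 11, Tapbp -0.23). Of the interferon genes, Rsad2, which encodes the antiviral enzyme viperin, went the other way, at 0.69 ± 0.23 (adjusted p = 0.672, higher in 6 of 6 libraries). The adjusted p of these 6 lists was 0.564 with an estimated correlation, and 0.695 for the interferon list; 0 of their members passed over all genes or adjusted over the list alone. Without ERKi 3 the calls of the circadian (median -0.19, adjusted p = 0.101) and pan Schwann lists (median -0.066, adjusted p = 0.445) were lost, and the nerve fibroblast median was -0.31 (adjusted p = 0.0148). The glucocorticoid call was lost without vehicle 4 (median -0.14, adjusted p = 0.244). With the neuron covariate the calls of the immediate early (median -0.068), chemokine (-0.23), pan Schwann (-0.11), interferon (-0.21), MHC class I (-0.052) and circadian lists (-0.16) were lost, with adjusted p from 0.0720 to 0.142.

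Lists that mark other tissues were higher after ERKi. Neuron genes were higher in 10 of 10 members (median 1.01, adjusted p = 0.564 with an estimated correlation). Without ERKi 3 the neuron median was 0.60 (adjusted p = 2.41e-04). Adipocyte genes were higher in 10 of 13 (median 0.83, adjusted p = 0.564 with an estimated correlation). Of these, 5 passed adjusted over the list alone and 0 over all genes, led by the triglyceride synthesis gene Dgat2 (1.10 ± 0.26) and the adipsin gene Cfd (2.01 ± 0.67). Skeletal muscle genes were higher in 15 of 17 (median 2.17, adjusted p = 0.695 with an estimated correlation), a call lost without ERKi 4 (median 1.11, adjusted p = 0.176). Of the neuron and muscle genes 0 passed over all genes or adjusted over the list alone. Mitosis genes had a median of -0.26 (24 of 30 lower, camera adjusted p = 0.0585) and E2F and DNA replication genes one of -0.03 (adjusted p = 0.587). The mitosis list was called without vehicle 4, where its median was -0.45, and also without vehicle 6, ERKi 3 or ERKi 6, where the medians were -0.40, -0.21 and -0.35.

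CDKi against vehicle asked what CDK4/6 inhibition alone changed. The clearest difference was in adipocyte genes, which were higher in 13 of 13 members with a median log2 fold change of 1.87 (camera adjusted p = 1.02e-32, adjusted p = 0.00101 with an estimated correlation). Adjusted over the list alone 9 members passed, against 0 over all genes. Dgat2 was at 17.8 CPM in CDKi and 6.11 CPM in vehicle (1.54 ± 0.26, adjusted p = 0.0736, higher in 6 of 6 libraries), and Plin1, which coats lipid droplets, at 7.35 and 1.27 CPM (2.51 ± 0.64, adjusted p = 1). Thrsp, a gene of lipid synthesis, had a log2 fold change of 1.87 ± 0.35 (adjusted p = 0.131, higher in 6 of 6 libraries). By edgeR's quasi-likelihood test 0 genes changed. The count at an unadjusted p under 0.05 was 480, DESeq2 called 58 genes (57 higher, 1 lower) and limma-voom called 0. The edgeR count was 1 without vehicle 1, 3 without ERKi 1 and 2 without ERKi 3.

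Mitosis genes were lower after CDKi in 25 of 30 members (median -0.28, camera adjusted p = 3.94e-04, adjusted p = 0.547 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. The call was lost with the adipocyte list as a covariate (median -0.013, adjusted p = 0.871) and, in a setting chosen after seeing the data, without the deepest and shallowest libraries (median -0.11, adjusted p = 0.207). The mitotic kinase gene Ttk was at -0.62 ± 0.31 and the kinetochore motor gene Cenpe at -0.36 ± 0.21. E2F and DNA replication genes, the transcripts controlled by the retinoblastoma protein, which CDK4/6 phosphorylates, had a median of -0.03 (21 of 35 lower, camera adjusted p = 0.392). Among them the helicase gene Mcm5 was at -0.19 ± 0.20 and the ribonucleotide reductase gene Rrm2 at -0.37 ± 0.34. Mki67 was at -0.55 ± 0.51, Top2a at -0.28 ± 0.60, Cdkn1a at -0.12 and Cdkn2c at 0.06, all with an adjusted p of 1. ERK pathway output genes had a median of 0.0028 (camera adjusted p = 0.622), with Dusp6 at 0.0028, Spry4 at -0.16, Etv5 at 0.07 and Ccnd1 at 0.0054. Postn was at -0.39.

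In all, 16 lists differed after CDKi by camera, 9 higher and 7 lower, and the adipocyte list alone also passed with an estimated correlation. Skeletal muscle genes were higher in 17 of 17 (median 3.90, adjusted p = 0.547 with an estimated correlation, 11 passed adjusted over the list alone and 0 over all genes), and CDKi 5 carried the highest level of that list. Tnnt3 and Ckm, which encode a troponin and muscle creatine kinase, had log2 fold changes of 5.17 ± 1.48 and 6.96 ± 2.04. Tnnt3 was at 13.36 ± 29.65 CPM in CDKi and 0.37 ± 0.22 CPM in vehicle, above the vehicle mean in 5 of 6 libraries. Ckm was at 21.87 ± 52.08 and 0.19 ± 0.22 CPM, above it in 3 of 6. A count of 3 was 0.0709 to 0.556 CPM in the vehicle libraries, so these vehicle levels lay near the floor and both fold changes are uncertain. Higher too were glucocorticoid response (10 of 12, Fkbp5 1.31 ± 0.43), immediate early (13 of 16, Junb 0.57 ± 0.22), endothelial (11 of 12, Tie1 0.53), p53 target (11 of 17, Phlda3 0.30), fatty acid synthesis (9 of 13, Fasn 0.33), pericyte and smooth muscle (10 of 12) and circadian clock genes (11 of 14, Per2 0.72). Lower were type I interferon response (19 of 22, Isg15 -0.93), extracellular matrix (26 of 28, median -0.23), macrophage (12 of 16, Folr2 -0.75), monocyte and neutrophil (3 of 4, Ccr2 -0.53), MHC class II (9 of 10, H2-DMb1 -0.59) and heat shock genes (10 of 11, Hspa1a -1.34). The adjusted p of these 13 lists was 0.547 with an estimated correlation, except 0.584 for extracellular matrix and 0.600 for macrophages. Over all genes 0 members of these lists passed, and adjusted over the list alone only Thrsp did. The members with the smallest p of the circadian and matrix lists went against their list. Npas2 of the circadian list was at -0.98 ± 0.38, above the vehicle mean in 0 of 6 libraries. The elastin gene Eln of the matrix list was at 0.71 ± 0.30, above the vehicle mean in 5 of 6 libraries. CDKi 5 stood apart on the pericyte list too, at 5.25 log2 CPM against 4.06 to 4.47 in the other CDKi libraries, and the desmin gene Des of that list was at 6.35 ± 9.95 CPM in CDKi and 1.89 ± 0.257 CPM in vehicle (1.74 ± 0.58, adjusted p = 1, higher in 4 of 6 libraries).

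Several of these calls after CDKi rested on single libraries, CDKi 5 among them, or changed with the adipocyte list as a covariate. That list was itself higher in CDKi (3.26 ± 0.543 log2 CPM) than in vehicle (1.41 ± 0.949). The covariate therefore takes up part of the contrast with vehicle, and changes under it cannot separate adipocyte content from treatment. Without CDKi 4 camera lost the macrophage (median -0.052, adjusted p = 0.271), monocyte (-0.13, 0.271) and MHC class II calls (-0.075, 0.257). The heat shock call was lost without vehicle 5 (-0.021, 0.798) and the p53 target call without CDKi 3 (0.066, 0.192). Without CDKi 3 the macrophage and MHC class II medians were larger, at -0.40 and -0.52, and called. Without CDKi 5 the calls of the skeletal muscle (median 0.68, adjusted p = 0.267), pericyte (0.041, adjusted p = 0.837), endothelial (0.075, 0.267), p53 target (0.091, 0.107), fatty acid (0.0041, 0.368), circadian (0.16, 0.211), macrophage (-0.053, 0.166), monocyte (-0.23, 0.107), MHC class II (-0.11, 0.107) and heat shock lists (-0.036, 0.267) were lost. With the adipocyte list as a covariate, endothelial and pericyte genes were called lower (medians -0.44 and -0.32, adjusted p = 0.00308 and 0.0410). Calls were lost with a median on the other side of 0 for the fatty acid (-0.054), glucocorticoid (-0.089), circadian (-0.039), macrophage (0.079), monocyte (0.0093), MHC class II (0.35) and heat shock lists (0.24), and on the same side for the immediate early (0.037), p53 target (0.19) and skeletal muscle lists (0.99). The interferon (-0.39, adjusted p = 0.00480) and extracellular matrix lists (-0.22, adjusted p = 0.00308) were called with that covariate. The interferon median was -0.17 without vehicle 5 (adjusted p = 0.0466), and the matrix call was lost without vehicle 5 (-0.14, adjusted p = 0.0558) or CDKi 1 (-0.11, adjusted p = 0.295).

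The combination against vehicle asked what both drugs changed together. ERK target genes fell: Etv4, an ETS transcription factor induced by ERK, dropped from 18.6 ± 5.57 CPM in vehicle to 6.14 ± 2.01 CPM (log2 fold change -1.60 ± 0.24 SE, adjusted p = 0.0169), and Spry4 from 59.7 ± 20.8 to 18.9 ± 10.1 CPM (-1.66 ± 0.33, adjusted p = 0.0399). By edgeR's quasi-likelihood test 19 of 15385 genes changed, 2 higher and 17 lower, each on the same side of the vehicle mean in 6 of 6 combination libraries. At an unadjusted p under 0.05 there were 1770 genes, DESeq2 called 279 (85 higher, 194 lower) and limma-voom 30 (4 higher, 26 lower). Genes of 3 matrix proteins outside the fixed matrix list fell: Thbs1, which encodes the matrix glycoprotein thrombospondin 1 (348 to 69.5 CPM, -2.33 ± 0.44, adjusted p = 0.0362), Fbn2, which encodes the microfibril protein fibrillin 2 (66.0 to 13.2 CPM, -2.32 ± 0.41, adjusted p = 0.0347), and the collagen gene Col9a2 (36.0 to 10.8 CPM, -1.73 ± 0.34, adjusted p = 0.0399). The zinc finger factor Egr3 (33.4 to 6.91 CPM, -2.28 ± 0.44, adjusted p = 0.0362) and the lectin-like receptor gene Klrb1a (24.7 to 6.40 CPM, -1.94 ± 0.38, adjusted p = 0.0399) fell as well. The genes that rose were Atf3, a stress-induced transcription factor (9.90 to 26.6 CPM, 1.42 ± 0.26, adjusted p = 0.0362), and Lzts3 (17.7 to 26.1 CPM, 0.56 ± 0.10, adjusted p = 0.0313). The remaining 10 genes that fell were Bank1, Pomk, Klra2, Fjx1, Timd4, Osgin2, BC039771, Megf10, Ccr1 and Arsb. They lie outside the rule for named genes and are named after their values were seen. Among them Timd4, a receptor of tissue macrophages for dying cells, had a log2 fold change of -2.60 ± 0.50 and the chemokine receptor gene Ccr1 one of -1.62 ± 0.33. Klrb1a and Klra2 belong to families of similar genes, and no strand setting of the counting is given, so values of such genes and of overlapping or antisense genes are uncertain.

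In the GRCm38 (mm10) annotation all of these named genes but BC039771, a long noncoding RNA, are protein-coding. Etv4 lies on chromosome 11 at 101769747 to 101785310, Spry4 on chromosome 18 at 38586247 to 38601347, Thbs1 on chromosome 2 at 118111876 to 118127133 and Fbn2 on chromosome 18 at 58008623 to 58210572. Egr3 lies on chromosome 14 at 70077317 to 70082613, Klrb1a on chromosome 6 at 128609227 to 128622934 and Col9a2 on chromosome 4 at 121039566 to 121055325. Atf3 lies on chromosome 1 at 191170296 to 191183333 and Lzts3 on chromosome 2 at 130632765 to 130642866. The values are deposited counts per gene.

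**Figure D2:**
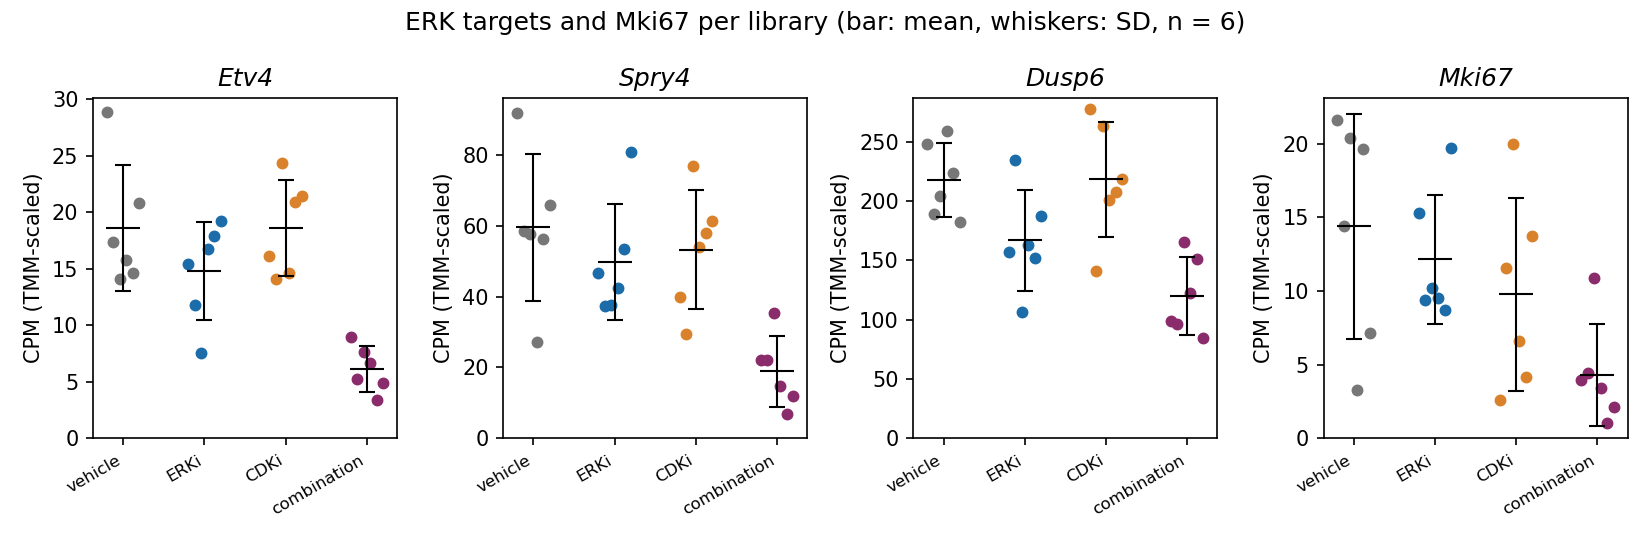
TMM-scaled CPM of Etv4, Spry4, Dusp6 and Mki67, with a point for each of the 6 libraries of every group, the mean as a bar and the SD as whiskers. The combination libraries lie between 3.41 and 8.99 CPM for Etv4, below all 6 vehicle libraries, which lie between 14.1 and 28.9 CPM.

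The 19 calls depended on which libraries and settings were used. Without the 3 liver-positive libraries there were 108 (13 higher, 95 lower), without the 6 neuron-poor libraries 0, with the neuron list as a covariate 37 (11 higher, 26 lower) and with the adipocyte list as a covariate 0, where Etv4 was at -1.69 (adjusted p = 0.0904, against 5.57e-07 to 0.255 over its alternatives). All but the adipocyte covariate were chosen after seeing the data. The adipocyte list was itself higher in the combination (2.75 ± 0.493 log2 CPM) than in vehicle (1.41 ± 0.949). A loss of calls with this covariate therefore cannot separate adipocyte content from treatment. The liver-positive libraries, ERKi 3, CDKi 1 and CDKi 3, are not part of this comparison. Leaving out these or any other ERKi or CDKi library acts on it only through the filter, scaling and spread shared by all libraries. Leaving out 1 library at a time gave 0 genes without combination 2 or 5 and 1 without vehicle 2, 3 or 5 or combination 6. It gave 2 without vehicle 1, 3 without ERKi 1, ERKi 4, CDKi 4 or combination 4, and 4 without vehicle 6. It gave 5 without CDKi 6, 6 without combination 1, 7 without CDKi 5, 54 without ERKi 3 and 94 without vehicle 4. Etv4 passed in 15 of 17 test settings, Atf3 and Fbn2 in 14, Lzts3 in 13, Spry4 and Thbs1 in 12, Egr3 and Klrb1a in 11 and Col9a2 in 10, each with the direction given above.

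As a group, ERK pathway output genes were lower in the combination in 18 of 21 members (median -0.33, camera adjusted p = 1.33e-12, adjusted p = 0.0229 with an estimated correlation). Over all genes 2 passed, and adjusted over the list alone 8 did, all lower: Etv4, Spry4, Egr1, Dusp6, Phlda1, Dusp4, Spred1 and Spry1. Dusp6 was at 120 ± 32.6 CPM against 218 ± 31.5 CPM in vehicle (-0.86 ± 0.19, adjusted p = 0.0690, lower in 6 of 6 libraries), Etv5 at -0.46 ± 0.22 (adjusted p = 0.417) and Ccnd1 at -0.16 ± 0.38 (adjusted p = 0.920). Mitosis genes were lower in 28 of 30 members (median -0.70, camera adjusted p = 3.47e-10, adjusted p = 0.291 with an estimated correlation), with 0 passing over all genes and 3 adjusted over the list alone: Ccnb1 (-2.72 ± 0.73), Mki67 (-1.75 ± 0.53, adjusted p over all genes 0.162) and Ttk. Ccnb1 was at 0.139 ± 0.061 CPM in the combination and 1.04 ± 1.01 CPM in vehicle. A count of 3 was 0.162 CPM in the deepest combination library, so that combination mean lay below the floor and the fold change is uncertain. With the adipocyte list as a covariate the mitosis median was -0.44 (adjusted p = 0.00177). Top2a was at -1.51 ± 0.62 (adjusted p = 0.333). E2F and DNA replication genes had a median of -0.06 (20 of 35 lower, camera adjusted p = 0.343), with Mcm5 at -0.07 and Rrm2 at -0.65, and the CDK4/6 axis one of -0.14 (adjusted p = 0.182), with Cdkn1a at -0.21 and Cdkn2c at 0.42; 0 members of either list passed over all genes or adjusted over the list alone.

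Extracellular matrix genes were lower in the combination in 26 of 28 members (median -0.81, camera adjusted p = 1.27e-17, adjusted p = 0.187 with an estimated correlation), with 0 passing over all genes and 20 adjusted over the list alone, 19 lower and 1, the elastin gene Eln, higher. Examples were the collagen gene Col6a2 (-1.55 ± 0.41), the tenascin gene Tnc (-1.22 ± 0.32) and Postn (-0.98 ± 0.42). Endothelial genes were higher in 12 of 12 members (median 0.79, camera adjusted p = 5.16e-11, adjusted p = 0.187 with an estimated correlation), with 0 passing over all genes and 11 adjusted over the list alone, among them the junction gene Esam (1.07 ± 0.25) and the von Willebrand factor gene Vwf (0.99 ± 0.30). With the adipocyte list as a covariate the endothelial median was 0.32 (adjusted p = 0.0396), and without combination 3 it was 0.51 (adjusted p = 1.45e-07). Cholesterol synthesis genes were lower in 20 of 21 (median -0.49, camera adjusted p = 4.83e-10, adjusted p = 0.306 with an estimated correlation), with 0 and 9 passing, such as Hmgcs1 (-1.01 ± 0.27) and Sc5d (-0.79 ± 0.23). Their median was -0.29 with the adipocyte covariate (adjusted p = 0.00792) and -0.22 without the 6 neuron-poor libraries (adjusted p = 0.00196). Myelin genes were lower in 20 of 21 (median -0.35, adjusted p = 0.568 with an estimated correlation), with 0 and 1 passing, Egr2 (-1.03 ± 0.28); Pmp2, a myelin fatty acid carrier, was at -1.95 ± 0.62. Without combination 2 the myelin median was -0.21 (adjusted p = 0.00313).

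Immune lists in the combination were lower for chemokines (13 of 16, median -0.71, adjusted p = 0.435 with an estimated correlation), macrophages (13 of 16, median -0.18, adjusted p = 0.6253) and monocytes and neutrophils (3 of 4, median -0.76, adjusted p = 0.483). Over all genes 0 members passed. Adjusted over the list alone 5 chemokine genes passed, 4 lower, such as Ccl2 (-2.30 ± 0.57), and 1 higher, Cxcl12 (0.91 ± 0.24); the macrophage genes Folr2 (-1.49 ± 0.45) and Lyve1 (-0.95 ± 0.30) passed too, and 0 monocyte and neutrophil genes. The monocyte call was kept in 4 of the 24 fits that left out 1 library. The macrophage call was lost without combination 1 (median -0.073, adjusted p = 0.0677) or 6 (-0.084, adjusted p = 0.0636), and the chemokine call without combination 1 (-0.56, adjusted p = 0.0505) or 6 (-0.50, adjusted p = 0.0841). Adipocyte genes were higher in 13 of 13 (median 0.95, adjusted p = 0.187 with an estimated correlation, Dgat2 0.95 ± 0.26 passed adjusted over the list alone) and muscle genes in 15 of 17 (median 2.75, adjusted p = 0.6253, 0 passing). Circadian clock genes were higher in 11 of 14 (median 0.32, adjusted p = 0.306 with an estimated correlation, 3 passing over the list alone, with Tef at 0.73 ± 0.19). Glucocorticoid response genes were higher in 10 of 12 (median 0.65, adjusted p = 0.6253, Lcn2, at 2.80 ± 0.67, passing over the list alone). The muscle call was lost without vehicle 4 or combination 1 or 4 (adjusted p = 0.0579, 0.137 and 0.191), and the glucocorticoid call without vehicle 1 or 3 or combination 4 or 5 (adjusted p = 0.0983, 0.0662, 0.103 and 0.202). In all, 13 lists were called, 5 higher and 8 lower, and the ERK list alone also passed with an estimated correlation.

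**Figure D3:**
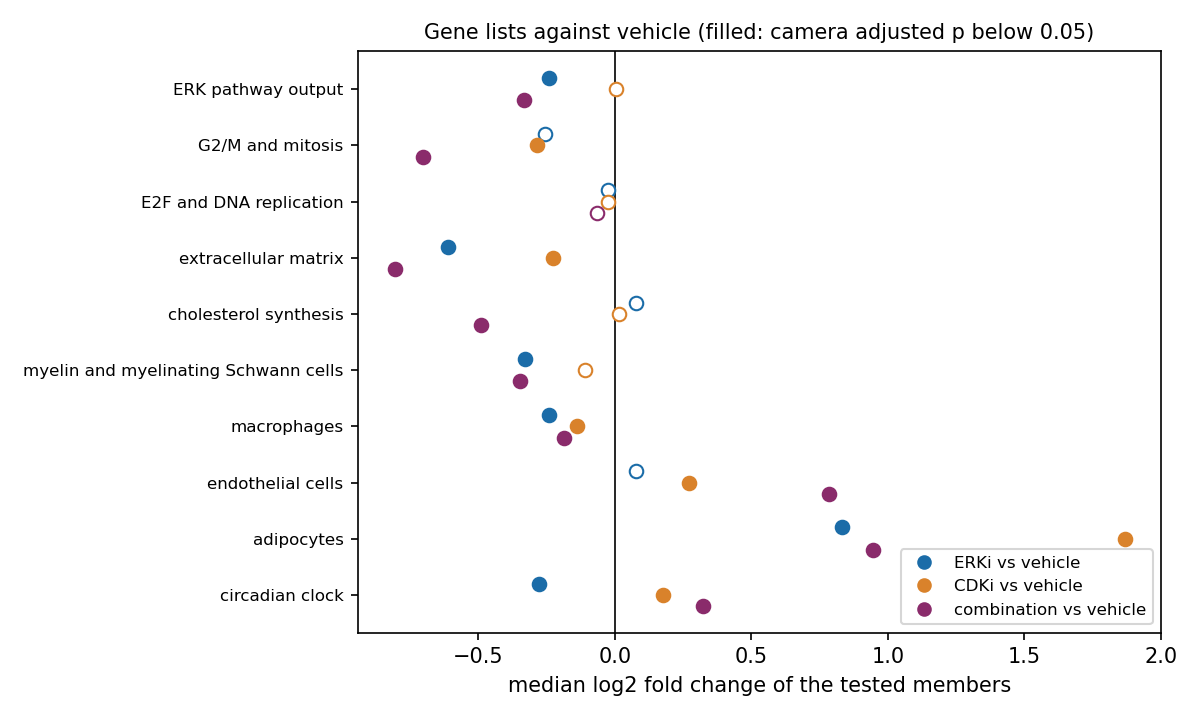
Median log2 fold change against vehicle of the tested members of 10 gene lists, with a point per treatment, filled where camera's adjusted p with a preset correlation is below 0.05. The ERK pathway output list lies at -0.24 in ERKi, 0.0028 in CDKi and -0.33 in the combination.

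Combination against ERKi asked what adding the CDK4/6 inhibitor changed. Circadian clock genes were higher in 11 of 14 members (median 0.45, camera adjusted p = 2.36e-08, adjusted p = 0.0445 with an estimated correlation), with 0 passing over all genes and 8 adjusted over the list alone. ERKi 3 stood apart on this list, at 4.86 log2 CPM against 5.30 to 5.56 in the other ERKi libraries. The median was 0.37 without ERKi 3 (adjusted p = 8.16e-07) and 0.28 with limma-voom (adjusted p = 4.26e-05). ERK pathway output genes were lower in 15 of 21 (median -0.24, camera adjusted p = 1.31e-06, adjusted p = 0.186 with an estimated correlation, 0 and 5 passing). Cholesterol synthesis genes were lower in 20 of 21 (median -0.58, adjusted p = 0.215 with an estimated correlation, 0 and 9 passing), endothelial genes higher in 12 of 12 (median 0.67, adjusted p = 0.215, 0 and 10 passing) and glucocorticoid response genes higher in 11 of 12 (median 1.24, adjusted p = 0.215, 0 and 8 passing). Neuron genes were lower in 10 of 10 (median -0.65, adjusted p = 0.836 with an estimated correlation). By edgeR's quasi-likelihood test 0 genes changed, with Etv4 at the smallest adjusted p, 0.221; 1437 genes had an unadjusted p under 0.05, DESeq2 called 71 (31 higher, 40 lower) and limma-voom 6 (3 higher, 3 lower). The edgeR count was 1 without ERKi 3. By camera 13 lists differed, 7 higher and 6 lower, and the circadian list alone also passed with an estimated correlation.

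Combination against CDKi asked what adding the ERK1/2 inhibitor changed. ERK pathway output genes were lower in 20 of 21 members (median -0.44, camera adjusted p = 1.96e-20, adjusted p = 0.00162 with an estimated correlation), with 1 passing over all genes and 10 adjusted over the list alone. The 1 gene was Etv4, which fell from 18.6 ± 4.22 to 6.14 ± 2.01 CPM (-1.60 ± 0.24, edgeR adjusted p = 0.0167, lower in 6 of 6 libraries). Extracellular matrix genes were lower in 26 of 28 (median -0.60, adjusted p = 0.285 with an estimated correlation, 0 and 5 passing), cholesterol synthesis genes in 20 of 21 (median -0.55, adjusted p = 0.259, 0 and 9 passing) and immediate early genes in 11 of 16 (median -0.33, adjusted p = 0.285, 0 and 8 passing, of which 7 lower and Atf3 higher). Endothelial genes were higher in 12 of 12 (median 0.53, adjusted p = 0.335 with an estimated correlation, 0 and 3 passing). At an unadjusted p under 0.05 there were 1087 genes; DESeq2 called 143 (18 higher, 125 lower) and limma-voom 4, all lower. E2F and DNA replication genes had a median of 0.02, while camera's direction for the list was down. Etv4 was no longer called without CDKi 3, 5 or 6 or combination 2, 4, 5 or 6, with 0 genes in each case; the count was 2 without ERKi 6, CDKi 1 or CDKi 2, 3 without combination 3 and 6 without ERKi 3.

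ERKi against CDKi gave 0 changed genes by edgeR, with 698 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. By camera 16 lists differed, 2 higher and 14 lower in ERKi, and 0 did with an estimated correlation (smallest adjusted p = 0.237). Glucocorticoid response genes were lower in ERKi in 11 of 12 members (median -0.94, adjusted p = 0.288 with an estimated correlation), immediate early genes in 15 of 16 (median -0.51, adjusted p = 0.287) and ERK pathway output genes in 19 of 21 (median -0.19, adjusted p = 0.380). Over all genes 0 of them passed, and adjusted over the list alone 3, 2 and 0 did. E2F and DNA replication genes had a median of -0.0012, while camera's direction for the list was up. Neuron genes were higher in ERKi in 10 of 10 (median 1.02, adjusted p = 0.388 with an estimated correlation).

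The interaction asked whether the combination departed from the sum of the single drugs' log2 changes. By edgeR 0 genes did, with 568 at an unadjusted p under 0.05, 0 by limma-voom and 155, all lower, by DESeq2, which tested 23421 genes. With no count filter, over the same 23421 genes, edgeR called 0. The edgeR count was 1 without ERKi 1. ERK pathway output genes lay below the sum in 16 of 21 members (median -0.24, camera adjusted p = 1.40e-06, adjusted p = 0.185 with an estimated correlation), with 0 passing over all genes and 2, Etv4 and Egr1, adjusted over the list alone. Adipocyte genes lay below the sum in 11 of 13 (median -2.54, adjusted p = 0.184 with an estimated correlation, 0 and 6 passing), cholesterol synthesis genes in 20 of 21 (median -0.58, adjusted p = 0.290, 0 and 0 passing), and type I interferon genes lay above it in 20 of 22 (median 0.79, adjusted p = 0.301, 0 and 0 passing). By camera 9 lists departed, 5 above and 4 below, and 0 with an estimated correlation. A greater effect of the combination on single ERK targets than the sum of both drugs was therefore not shown over all genes.

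The comparisons with vehicle share their control libraries, which alone correlates their fold changes. Over 15385 genes r was 0.24 between ERKi and CDKi, 0.52 between ERKi and the combination and 0.49 between CDKi and the combination. Simulated unchanged groups, drawn around the mean of these same vehicle libraries, gave 0.090, 0.085 and 0.081. The covariances were 0.0324, 0.0863 and 0.0548 against simulated 0.00589, 0.00561 and 0.00532. Drawn this way, the simulated fold changes leave out the error of the vehicle mean, which is what shared controls add. The simulation therefore cannot tell shared controls from shared drug effects, and no conclusion is drawn from values above it. With the vehicle libraries split between the members of a pair, the mean r over 20 splits was -0.06 (range -0.63 to 0.30), 0.17 (-0.42 to 0.45) and 0.0051 (-0.42 to 0.24). With 0 calls in ERKi and in CDKi, the overlap of calls could not be assessed.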

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

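The tests on neuron and liver transcripts were all chosen after these transcripts had been seen. Within each group of 6, a library was listed where its distance from the nearest other library took most of the group's range. Of 220 groups of values 16 were listed, and chance lists about 1 in 20.

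ERKi 3 stood apart on the most measures. Its Rn45s share was 6.08% of counts (others 1.45 to 2.08%), its mean log2 CPM was 6.95 for myelin genes (others 8.35 to 9.03), 7.69 for pan Schwann cells (8.52 to 8.75), 5.17 for receptor tyrosine kinases and ligands (5.61 to 5.87) and 4.86 for circadian clock genes (5.30 to 5.56). It was higher than the others for dendritic cells at 2.51 (1.87 to 1.98), neurons at 9.55 (7.66 to 8.32) and heat shock genes at 6.64 (6.08 to 6.28). In megacounts, the total stood apart in vehicle 2 at 42.3 (42321550 counts, others 5.39 to 19.1) and in ERKi 6 at 24.7 (24676846 counts, others 14.5 to 17.3). On mean log2 CPM, CDKi 5 was high for pericytes and smooth muscle at 5.25 (others 4.06 to 4.47), CDKi 3 high for macrophages at 5.28 (3.99 to 4.42) and combination 5 low for heat shock genes at 5.71 (6.00 to 6.17). On log2 CPM, Etv5 was low in CDKi 2 at 5.46 (others 5.83 to 6.06), Klrb1a high in combination 1 at 3.66 (2.13 to 2.66) and Col9a2 low in vehicle 4 at 3.55 (5.03 to 5.74).

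The mean log2 CPM of the neuron list differed between libraries by 8.03. Treatment as its source was argued against, since the vehicle libraries alone spanned 6.55, and so was depth, since the range was 7.74 with every library thinned to one depth. Over the 18 neuron-rich libraries the satellite glia list, 8 genes of which 2 are also on the pan Schwann list, followed the neuron list with Pearson r = 0.679 (permutation p = 0.00224) and Spearman rho = 0.62 (permutation p = 0.00711), the only relation computed in this family, with r = 0.568 without the 2 farthest libraries. Within the 9 libraries with titles in the 4000s r was 0.583, within the 9 in the 5000s 0.844, and with group means taken out 0.76. A candidate source is ganglion tissue carried with some of the nerves; a difference between animals was not tested.

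Alb, which is outside the fixed lists and counts as a liver gene, was at 4543 CPM in ERKi 3, 3155 CPM in CDKi 1 and 4534 CPM in CDKi 3, above every vehicle library. Treatment as its source was argued against, since at most 2 of the 6 libraries of a treated group held liver transcripts. All 8 tested liver genes, including Apob at 1511, 1001 and 1440 CPM, were over 10-fold above the median of the other libraries in all 3, and the SD over genes of the log2 ratio between these libraries was at most 0.175. Of these genes, Cyp2e1 was at up to 95.4 CPM in the other libraries. RNA from liver tissue may have entered these 3 libraries; the step at which it did was not tested.

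Xist and Y-linked transcripts occurred together in CDKi 2, at 767 and 219 CPM, in ERKi 3, at 882 and 16.2 CPM, and in CDKi 3, at 3037 and 16.6 CPM; whether these libraries hold RNA of more than 1 animal, through mixing or carry-over, was not tested, and their values and the term for sex carry that doubt.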

How the results depend on the processing

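The neuron covariate, equal depth, leaving out single libraries for lists other than the ERK, E2F and mitosis lists, and leaving out the liver-positive, neuron-poor, deepest or shallowest libraries were chosen after seeing the data. No paired analysis was possible because the titles give every sample its own number and none recurs in another group. In the combination the ERK list kept its call and direction in 16 of 16 settings of the test (medians -0.48 to -0.30), as did the mitosis (-0.88 to -0.44), extracellular matrix (-0.93 to -0.74), cholesterol (-0.52 to -0.22), myelin (-0.52 to -0.28) and endothelial (0.32 to 0.87, highest adjusted p = 0.0396) lists. The ERK list against CDKi (-0.57 to -0.36) and the circadian list against ERKi (0.28 to 0.47) did too. These 16 settings, and the fits that left out 1 library, all used camera with the preset correlation. Whether a call with an estimated correlation holds across them was not tested. The 16 settings leave out camera with an estimated correlation and fry. In the combination against vehicle the ERK list kept its call under both (adjusted p = 0.0229 and 0.00214), while the mitosis (0.291 and 0.115), extracellular matrix (0.187 and 0.0666), cholesterol (0.306 and 0.133), myelin (0.568 and 0.364) and endothelial lists (0.187 and 0.0666) lost theirs. Other lists were called in fewer settings, or in fewer of the 24 fits that left out 1 library, the number of these given second. They were called in ERKi for the lists pan Schwann 5 of 16 and 14, interferon 8 of 16 and 19, chemokine 9 of 16 and 19, immediate early 9 of 16 and 20, muscle 12 of 16 and 21, circadian 11 of 16 and 21, ERK 11 of 16 and 22, MHC class I 10 of 16 and 22, macrophage 13 of 16 and 23, glucocorticoid 15 of 16 and 23, myelin 15 of 16 and 24, nerve fibroblast 14 of 16 and 24, adipocyte 15 of 16 and 24, neuron 14 of 16 and 24. They were called in CDKi for the lists monocyte 10 of 15 and 14, fatty acid 6 of 16 and 15, p53 target 9 of 16 and 17, pericyte 9 of 16 and 18, macrophage 12 of 16 and 18, MHC class II 10 of 16 and 18, circadian 10 of 16 and 19, heat shock 8 of 16 and 21, extracellular matrix 16 of 16 and 22, endothelial 14 of 16 and 22, muscle 13 of 16 and 23, immediate early 12 of 16 and 24, mitosis 14 of 16 and 24, adipocyte 15 of 16 and 24, interferon 15 of 16 and 24, glucocorticoid 13 of 16 and 24. They were called in the combination for the lists monocyte 8 of 15 and 4, glucocorticoid 13 of 16 and 20, muscle 12 of 16 and 21, macrophage 15 of 16 and 22, chemokine 15 of 16 and 22, adipocyte 15 of 16 and 24, circadian 13 of 16 and 24. The endothelial and pericyte numbers in CDKi include the adipocyte covariate, where the call was in the other direction. The sign of the median changed for 0 of the called lists in the fits that left out 1 library. Of 56 called results, 16 reversed in at least 1 of 19 alternatives. A count of 3 was 0.556 CPM in vehicle 3, the shallowest library, and 0.0709 CPM in vehicle 2, the deepest, so levels below these values were not detectable there. Where no cause is named, the cause was not tested.

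Counts of changed genes moved by over 1.5 times as follows. DESeq2, which tested more genes (23421 against 15385), called 11 (ERKi), 58 (CDKi), 279 (combination), 71 (combination vs ERKi), 143 (combination vs CDKi) and 155 (interaction). In the same order, edgeR with no count filter called 0, 1, 6, 0, 1 and 0 of these 23421 genes. These counts argue against the number of genes tested as the only source of the higher DESeq2 counts. Limma-voom called 30, 6 and 4 in the combination against vehicle, ERKi and CDKi. For the combination against vehicle the count of 19 became 6 with no count filter (more genes tested), 10 with only the groups compared (fewer samples), 43 with a sex term, 12 with the muscle covariate, 0 with the adipocyte covariate and 37 with the neuron covariate. It became 108 without the 3 liver-positive libraries, 0 without the 6 neuron-poor, 1 without the deepest and shallowest, 206 without the liver-positive and with the neuron covariate, and 31 at equal depth. Against CDKi the count of 1 became 0 with only the groups compared, without the neuron-poor libraries and at equal depth, and 2 without the liver-positive libraries and with the neuron covariate. Against ERKi it became 1 without the deepest and shallowest libraries. In CDKi it became 1 with no count filter or the neuron covariate, in ERKi 1 and in the interaction 3 with the adipocyte covariate.

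The ERK list in ERKi lost its call with limma-voom (median -0.070, adjusted p = 0.0533), no count filter (-0.22, 0.0560), the adipocyte covariate (-0.24, 0.0618), an estimated correlation (-0.24, 0.564), fry (-0.24, 0.526), without the neuron-poor libraries (-0.068, 0.176) and without the liver-positive libraries with the neuron covariate (-0.14, 0.128). The mitosis list in ERKi gained a call with the title series term (-0.34, adjusted p = 0.00457), the sex term (-0.29, 0.0121), without the liver-positive libraries (-0.21, 0.0143) and with the neuron covariate in addition (-0.16, 0.0355). The mitosis list in CDKi lost its call with the adipocyte covariate (-0.013, adjusted p = 0.871), an estimated correlation (-0.28, 0.547), fry (-0.28, 0.740) and without the deepest and shallowest libraries (-0.11, 0.207). In the combination it lost it with an estimated correlation (-0.70, adjusted p = 0.291) and fry (-0.70, 0.115).

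Leaving out 1 library at a time gave 0 to 94 genes for the combination, 0 to 3 for CDKi, 0 to 1 against ERKi, 0 to 6 against CDKi and 0 to 1 for the interaction; the libraries are named with each comparison. ERK list medians ranged from -0.29 to -0.090 in ERKi, -0.031 to 0.087 in CDKi, -0.49 to -0.30 in the combination and -0.61 to -0.34 in the combination against CDKi. Mitosis medians ranged from -0.45 to -0.10, -0.55 to -0.16 and -0.92 to -0.58 in ERKi, CDKi and the combination, and E2F medians from -0.081 to -0.017, -0.047 to 0.014 and -0.090 to 0.028.

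Log2 values at 0 or on the other side of it were these. With limma-voom, for ERKi vs vehicle Etv5 -0.12, Mki67 0.18, Top2a 0.24, Cdkn1a 0.026, immediate early list 0.017, and for CDKi vs vehicle Etv5 -0.0036, E2F list 0.0026. With upper quartile scaling, for CDKi vs vehicle Dusp6 -0.00095, Ccnd1 -0.012, ERK output list -0.0072. With no count filter, for CDKi vs vehicle monocyte list 0, and for combination vs vehicle monocyte list 0.68. With a term for the title series, for CDKi vs vehicle Dusp6 -0.0022, ERK output list -0.0022. With a sex term, for CDKi vs vehicle Ccnd1 -0.015, ERK output list -0.011. With the muscle covariate, for CDKi vs vehicle fatty acid list -0.019, muscle list -0.038, and for combination vs vehicle Acta1 -0.094, E2F list 0.0089. With the adipocyte covariate, for ERKi vs vehicle Top2a 0.17, and for CDKi vs vehicle Dusp6 -0.30, Ccnd1 -0.21, Top2a 0.32, Cdkn2c -0.55, Fasn -0.010, Plvap -0.51, Myh11 -0.39, Fcgr1 0.040, Mmp9 0.21, Plin1 -0.14, ERK output list -0.064, fatty acid list -0.054, endothelial list -0.44 (adjusted p = 0.00308), pericyte list -0.32 (adjusted p = 0.0410), macrophage list 0.079, monocyte list 0.0093, adipocyte list -0.14, MHC class II list 0.35, glucocorticoid list -0.089, circadian list -0.039, heat shock list 0.24, and for combination vs vehicle Cdkn2c -0.043, adipocyte list -0.21. With the neuron covariate, for ERKi vs vehicle Etv5 -0.057, Ccnd1 0.045, Top2a 0.044, Cdkn2c 0.0023, neuron list -0.0021, and for CDKi vs vehicle Dusp6 -0.011, ERK output list -0.011. Without the 3 liver-positive libraries, for ERKi vs vehicle Etv5 -0.082, and for CDKi vs vehicle Dusp6 -0.17, Ccnd1 -0.021, Cdkn2c -0.012. Without the 6 neuron-poor libraries, for ERKi vs vehicle Etv5 -0.018, Ccnd1 0.16, Mki67 0.13, Top2a 0.13, and for CDKi vs vehicle Postn 0.073, Etv5 -0.012, Hspa1b 0.25, heat shock list 0.044. Without the deepest and shallowest libraries, for ERKi vs vehicle Nf1 -0.0065, and for CDKi vs vehicle Dusp6 -0.067, Ccnd1 -0.048, Cdkn2c -0.025, ERK output list -0.048, fatty acid list -0.0095, and for combination vs vehicle monocyte list 0.25. Without the liver-positive libraries and with the neuron covariate, for ERKi vs vehicle Etv5 -0.21, Ccnd1 0.0068, Cdkn2c 0.13, pan Schwann list 0.030, and for CDKi vs vehicle Dusp6 -0.15. At equal depth, for CDKi vs vehicle Dusp6 -0.020, ERK output list -0.020, and for combination vs vehicle E2F list 0.063. The adipocyte, muscle and neuron lists were near 0 under their own covariate by its construction. For the others the cause was not tested.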

Other observations

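The test of the ERK list against CDKi and its alternatives as explanations were chosen after seeing the result; the counts of splits were planned.

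The lists of these 6 other cell types were not called against vehicle in any treatment. Non-myelinating and repair Schwann cell genes had medians of -0.06 in ERKi, 0.0035 in CDKi and 0.13 in the combination (camera adjusted p = 0.618, 0.865 and 0.183), with 1 of 14 members passing over all genes in the combination, Atf3, and the same 1 adjusted over the list alone. Mast cell genes had medians of -0.30, 0.18 and -0.54 (adjusted p = 0.370, 0.178 and 0.350) and perineurial genes of -0.10, 0.06 and 0.34 (adjusted p = 0.220, 0.343 and 0.372); in the combination the glucose transporter gene Slc2a1 and Crabp2 passed adjusted over the perineurial list alone, 1 higher and 1 lower, and 0 over all genes. T and NK cell genes (5 tested) had medians of -0.12, -0.22 and 0.68 (adjusted p = 0.932, 0.382 and 0.404), B and plasma cell genes (3 tested) of 0.47, -0.10 and 0.26 (adjusted p = 0.770, 0.729 and 0.343) and dendritic cell genes (6 tested) of -0.07, -0.15 and 0.23 (adjusted p = 0.870, 0.523 and 0.569). Adjusted over the list alone, Klrb1c of the T and NK list and Sdc1 of the B and plasma list passed in the combination, both lower, and 0 dendritic cell genes did; 0 passed over all genes. For these 3 lists in the combination, and for B and plasma cells in ERKi, camera's direction was down while the median was above 0; for T and NK cells in ERKi it was up while the median was below 0. It was also down against a median above 0 for pan Schwann cells in the combination (0.02, adjusted p = 0.383), and in CDKi for repair Schwann cells (0.0035) and neurons (0.05, adjusted p = 0.683).

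Receptor tyrosine kinases and their ligands had medians of -0.15, 0.05 and -0.02 (adjusted p = 0.159, 0.392 and 0.336), with Egfr, the epidermal growth factor receptor gene, lower in the combination adjusted over the list alone and 0 over all genes. Lists called in a single drug had in the combination a median of 0.07 for type I interferon response (adjusted p = 0.513), -0.12 for MHC class I presentation (0.240), -0.06 for MHC class II presentation (0.180), -0.10 for heat shock (0.372), 0.07 for p53 targets (0.324), 0.37 for neurons (0.332), -0.27 for nerve fibroblasts (0.0712) and -0.06 for immediate early genes (0.122). Adjusted over the list alone, 1 MHC class I gene (Calr), 1 heat shock gene (Hspa5), 3 nerve fibroblast genes, 3 immediate early genes and 0 of the MHC class II, p53 and neuron genes passed. Of these lists' genes, Atf3, higher, and Egr3, lower, passed over all genes, both on the immediate early list.

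ERK pathway output genes were lower in the combination (median -0.33). RNA from adipose tissue was argued against for the list only, which was at -0.30 and still called with the adipocyte list as a covariate. That call is by camera with a preset correlation, which called 13 of 33 lists in this comparison. With the same covariate 0 single genes were called, a loss that cannot separate adipocyte content from treatment. Depth was argued against, since the list was at -0.37 and called with all libraries thinned to one depth. The list was also lower in the combination than under CDKi alone (median -0.44, adjusted p = 0.00162 with an estimated correlation). This is not independent support, since the combination libraries are the same and the list in CDKi lay near vehicle (median 0.0028). Inhibition of ERK1/2 is only a candidate explanation. The list and its test against vehicle were fixed before the data were examined. The tests of this explanation were chosen after seeing the result, and on the same data. ERKi alone gave a smaller median of -0.24, not called with an estimated correlation. Without the 6 neuron-poor libraries the ERKi median was -0.068. A greater effect of both drugs than their sum was not shown with an estimated correlation (adjusted p = 0.185).

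Other splits of the libraries into groups of the same sizes were fitted, 100 per comparison with the real one. For the combination against vehicle 2 of 100, the real one included, gave as many as the real 19 genes, and the highest other split called 762. For the combination against CDKi 4 of 100, the real one included, gave as many as the real 1 gene, with 5 in the highest other. For the other 5 comparisons the real count was 0, which all 100 splits reach by construction, so these counts of splits say nothing about chance; the highest others were 1 (ERKi against vehicle), 64 (CDKi against vehicle), 0 (combination against ERKi), 64 (ERKi against CDKi) and 442 (interaction). By the count at an unadjusted p under 0.05, 13 of 100 splits were as large for the combination against vehicle, 38 for the combination against CDKi and 15 to 53 for the others. For the combination against vehicle and against CDKi, few splits reached the real number of genes called, but this did not exclude chance. That number fell to 0 without some single libraries, and the counts of 2 and 4 splits were not adjusted for the number of comparisons. By the count at an unadjusted p, more splits were as large as the real one, 13 and 38 of 100. Splits that call several times the real count point to a structure of the samples other than treatment.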
